A study of Rattus norvegicus with 20 samples.

How the data were processed

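Total RNA from the left ventricle of male SHHF rats, a hypertensive strain in which homozygous carriers of a defective leptin receptor become obese, had been copied into radiolabelled cDNA and hybridised to nylon membranes spotted with rat cDNA clones, per the labels. There were 20 arrays, each treated as 1 rat, in 4 groups of 5: obese and lean rats aged 4 months and obese and lean rats aged 10 months. Each array file held a grid of 240 lines by 240 columns, or 57600 spots, as 2304 blocks of 5 by 5 spots. Each block carried 12 clones spotted in duplicate around a centre spot without a clone, so that 27648 clones were measured.

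Per the file headers, the deposited values were the mean intensity of each spot, its local background level and their difference, with no normalization. The image software was not given in the sources used here. The series matrix deposited by the authors held the same background-subtracted intensity. Its values under 1 had been raised to 1 and each array scaled to a geometric mean of 10000, as found from the values themselves and not stated in the labels. On each array at least 99.74% of the matrix values were recovered by that rule within a relative tolerance of 1e-04. The matrix was linear, with no centring of genes, and ran through the grid in the reverse order of the array files. Its column medians lay between 6783 and 10246.

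The starting values were the mean spot intensity and the background. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, centre spots were then removed, and the log2 intensities were quantile-normalized over the 20 arrays. The 2 spots of a clone were averaged. A linear model with 1 mean per group was fitted to all 27648 clones with lmFit, and 6 contrasts were tested with eBayes using an intensity trend. The p values were two-sided and adjusted by Benjamini-Hochberg over all clones, with 0.05 as the threshold. Throughout, a difference is the first group minus the second on the log2 scale, ± gives the standard error of a fitted difference, and a group value is a mean ± SD with n = 5 arrays. The contrasts were obese against lean at each age, the difference between those effects, their average, and 10 against 4 months in lean and in obese rats. Preparation and plotting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

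Gene names came from the platform annotation. It gave 1 gene for 9068 clones (6841 genes), several genes for 83 and none for 18497, and none was named from a clone with several. In all, 1697 genes had more than 1 clone, and the clone with the highest mean signal stood for such a gene. The placement of the names on the grid was checked with 108 clones of 6 lists of abundant transcripts. Their mean signal lay at percentile 62.8 against 47.5 for all named clones, and z was 5.66 in the placement used against at most 4.04 in the other placements among 18432 tried. The clones of a gene nevertheless hardly went together. The Spearman correlation of mean signal between 2 clones of a gene was 0.04 over those 1697 genes, and the correlation of their log2 differences was 0.01 for age in obese rats and -0.02 for obesity at 4 months, across genes that are not independent replicates. The abundant lists thus favoured the placement used, but the clones of a gene did not bear out the map from clones to genes. That map stays in doubt. Every gene named here is a clone that carries that name in the annotation, and if the map is wrong, the list and marker results do not measure the named pathways or cell types.

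The lists, contrasts, named-gene rule and first set of other settings were fixed before the data were examined. Per contrast, genes were eligible for naming if they were among the 12 largest differences per direction past the threshold (6 for the age contrasts and the interaction), leaving out genes whose clones disagreed in sign. Where fewer than 10 genes passed, the 10 smallest p values per direction were added and are reported as not passing. The rule also took up to 4 members of each list with the smallest p, and 13 genes always, of which 5 were measured. The genes printed are a part of those eligible, apart from clones named for their position in the spotting block.

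The 21 gene lists were fatty acid oxidation, PPAR alpha targets and fatty acid handling, fatty acid and triglyceride synthesis, glycolysis and glucose uptake, citric acid cycle, oxidative phosphorylation, glutamine and amino acid metabolism, cardiac stress and fetal genes, sarcomere, calcium handling and excitation, extracellular matrix and fibrosis, antioxidant and oxidative stress, heat shock and chaperones, insulin and leptin signalling, renin-angiotensin with adrenergic and natriuretic signalling, inflammation and immune response, apoptosis and cell death, ubiquitin and proteasome, cytosolic ribosomal proteins, mitochondrially encoded genes, and clock genes. The 12 marker lists were cardiomyocyte, atrial muscle, fibroblast, endothelial cell, smooth muscle cell, macrophage and neutrophil, lymphocyte, red blood cell, adipocyte, skeletal muscle, lung and liver. Lists with at least 5 measured genes, 20 gene lists and 4 marker lists, were tested with camera (preset correlation 0.01) and adjusted within each kind, with the estimated correlation and fry beside it. Members were also adjusted over the list alone.

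The median ratio of spot intensity to background was 1.57 to 2.59 per array at 4 months and 1.12 to 1.54 at 10 months, so it parted the ages. In the centre spots it was 1.25 to 1.75 and 1.06 to 1.24. The share of clones above the 95th percentile of the centre spots was 11.2% to 90% per array, with a median of 47.25%. The correlation of duplicate spots was 0.82 to 0.93. The number of arrays limits the precision, and so do run pair and membrane differences, which the fit without blocks leaves in the residual spread. In that fit the median standard error of an obese-lean difference at 1 age was 0.29. The median 95% interval was ±0.59, a 1.5-fold difference. The steps were tested on simulated data with changes added to 100 clones of each size. At 4 months 31% of clones changed 2-fold and 100% of those changed 4-fold were recovered, with 5 unchanged clones called. At 10 months the shares were 29% and 98%, with 8 unchanged clones called, and for age in lean rats 39% and 99%, with 7. A shift of 0.5 in the 23 members of the oxidative phosphorylation list was found at an adjusted camera p of 7.46e-24 at 4 months and 4.4e-13 at 10 months. The simulated noise was independent between genes and arrays, without run pair or membrane effects. These shares and p values thus test the steps and do not give the recovery in the real arrays.

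The headers placed each obese array beside 1 lean array of the same age, giving 10 run pairs, of which 8 shared a header date, 1 was a day apart and 1 lacked a day. They also gave the second 10-month obese array that the labels number 3 (called replicate 3b) the number 4, and it was kept as a separate rat. From the geometry of the spots, the 10 arrays of each age were parted into 2 groups, a number set in advance, and 5 arrays fell in each. These groups are called membranes here. The correlation of spot geometry within a membrane had a median of 0.59 at 4 months (0.47 to 0.74) and 0.55 at 10 months (0.39 to 0.68). Between the membranes of an age it was 0.37 (0.29 to 0.44) and 0.4 (0.32 to 0.48), so the ranges overlapped at 10 months. All 10 arrays of each age were nearer on average to their own membrane, but the same correlations had formed the groups, so this adds no support. No run date held arrays of both ages. Membranes were sought within each age, so whether the ages shared them was not decided by that search. Between ages the geometry correlated at up to 0.49, and grouping all 20 arrays into 2 put 5 arrays of each age in both groups, while 4 groups parted the ages. The differences in signal between these 2 geometry groups correlated at only 0.05 between the ages, where the same 2 membranes should give the same differences, so sharing stays open. Run pair and membrane were fitted as blocks for obesity, and as random blocks for all contrasts.

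The 41 settings fixed in advance changed the background correction, normalization, clone filter, starting table, variance model, array weights, blocks, threshold, arrays in the fit, list correlation and value per gene, and left out each array in turn. A further 12 settings were chosen after seeing the data: membrane alone and with run pair as blocks, run pair as a block with each age fitted alone, the 2 geometry groups as a term, run pair and membrane as random blocks, both 4-month arrays numbered 1 left out or exchanged, all 4 arrays numbered 1 left out, local trends on the membrane removed, position in the block centred, and named clones alone. Outlying values within groups were sought with Dixon's ratio (critical value 0.71 for 5 arrays), and 100 splits of the arrays, the real one included, were used per contrast. The other columns of the array files were not used here.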

Results

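Left ventricular transcripts were measured in obese and lean male SHHF rats at 4 and at 10 months, with 5 macroarrays of 27648 rat cDNA clones in each of the 4 groups. The labels number 2 of the obese 10-month arrays 3, and both were kept as separate rats because the header of 1 of them gave the number 4. The labels place dilated cardiomyopathy in the obese animals from 10 months, so the older group stood at the age at which it begins. Median spot intensity ran from 903 to 3613 image units per array over a median background of 455 to 3224. The arrays numbered 1 at 10 months had the lowest ratios of intensity to background, 1.12 in the lean and 1.17 in the obese rat. All genes are named by the annotation of their clones. Since different clones of 1 gene barely went together (Spearman correlation 0.04 for mean signal), each value belongs to the clone, and the list and marker results hold only as far as that annotation does.

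The first question was how the ventricles of obese and lean young rats differed. In this strain obesity comes with the defective leptin receptor, so the obese-lean contrasts cannot tell one from the other. At 4 months the natriuretic peptide gene Nppb, a marker of wall stress, read 10.14 ± 0.48 (SD, n = 5) in obese and 10.24 ± 0.43 in lean rats on the normalized log2 scale, a difference of -0.1 ± 0.28 (SE). The calcium pump gene Atp2a2 differed by 0.14 ± 0.35, the pyruvate dehydrogenase kinase gene Pdk4 by 0.08 ± 0.27, the carnitine palmitoyltransferase gene Cpt1b by -0.17 ± 0.27 and the glutamine synthetase gene Glul by -0.31 ± 0.24, with obese replicate 3 at 9.61 and the next array at 10.93. Without that array the Glul difference was -0.02. The 95% interval of each of these 5 differences included 0, with and without run pair and membrane as blocks. The leptin receptor gene Lepr and Nppa, Myh6, Myh7, Ucp3, Slc2a4, Col1a1 and Col3a1 had no clone annotated with that gene alone.

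With limma, 0 of 27648 clones passed between obese and lean rats at 4 months, while 384 (1.39%) had an unadjusted p under 0.05, fewer than the median of 1544 in other splits of the same arrays. The real split set 1 obese against 1 lean array in each run pair, while other splits could break the pairs. The fit without blocks left pair differences in the residual spread, so the lower count does not show that obese and lean rats were unusually alike. The lowest p among named genes belonged to Pbxip1, which codes for a protein that binds PBX transcription factors. It differed by -0.81 ± 0.24 and was lower in the obese rat in all 5 run pairs, with an adjusted p of 1. With membrane and run pair as blocks its difference was -0.88. Ppfia1, for a scaffold protein of cell adhesions, differed by -0.8 ± 0.26 and was likewise lower in 5 of 5 run pairs. The mitochondrial transcription factor gene Tfam differed by -0.75, the dystroglycan gene Dag1 by -0.82, the lysophosphatidic acid receptor gene Lpar3 by -0.73 and the NF-kappa-B inhibitor gene Nfkbie by -0.59. On the higher side, the membrane-shaping protein gene Fnbp1 differed by 0.82 ± 0.28, the RNA-binding protein gene Rbm14 by 0.76, Susd6 by 0.68 and the nuclear kinase gene Hipk1 by 0.65. Rbm14, Susd6 and Hipk1 were higher in the obese rat in 5 of 5 run pairs. The other clone of Dag1 had the opposite sign. None of these passed the adjustment, each with an adjusted p of 1.

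The citric acid cycle list had a mean difference above 0, obese minus lean, at 4 months, without passing the test. All 11 measured members had a positive difference, with a mean of 0.17, but the mean was positive in 3 of 5 run pairs and ran from -0.18 to 0.6 between them. Its camera p was 0.0129 and its adjusted p 0.258, the lowest of the 20 gene lists tested, and with the estimated correlation the adjusted p was 0.774. With membrane and run pair as blocks the mean was 0.12. Within it, the succinyl-CoA ligase gene Sucla2 differed by 0.58 ± 0.32, and by 0.25 without lean replicate 5. Glycolysis and glucose uptake (13 measured genes) had a mean of -0.11 that was below 0 in 5 of 5 run pairs, with 9 members lower and an adjusted p of 0.945. The glycolytic enzyme gene Aldoc differed by -0.5 ± 0.3. Glutamine and amino acid metabolism had a mean of -0.14 over 8 genes.

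Of the other lists at 4 months, fatty acid oxidation had a mean of 0.07, insulin and leptin signalling 0.06, calcium handling 0.04, clock genes 0.03, oxidative phosphorylation 0.02 and cardiac stress genes 0.02. Means were 0.01 for fatty acid and triglyceride synthesis and for ribosomal proteins, and 0 for heat shock. They were -0.01 for antioxidant genes and apoptosis, -0.02 for PPAR alpha targets and sarcomere genes, -0.03 for ubiquitin and proteasome genes, -0.04 for extracellular matrix genes and -0.08 for both inflammation and renin-angiotensin signalling. The means of the PPAR alpha list, fatty acid synthesis, cardiac stress, heat shock, apoptosis, ribosomal protein, antioxidant, oxidative phosphorylation and clock lists differed in sign from their median or test, or 1 of these was 0. Single members with larger differences were Rpl21 of the ribosome (0.78 ± 0.31), Camk2d, a calcium-dependent kinase (0.46 ± 0.25), Psmd8 of the proteasome (-0.73 ± 0.35), the fatty acid sensor gene Ppara (-0.59 ± 0.31) and the mineralocorticoid receptor gene Nr3c2 (-0.55 ± 0.29). The other clones of Rpl21 and Glul had the opposite sign. Camera and fry passed 0 of 20 gene lists with either correlation, with 1 list at an unadjusted camera p under 0.05, and adjusted over the list alone 0 members passed.

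**Figure D1:**
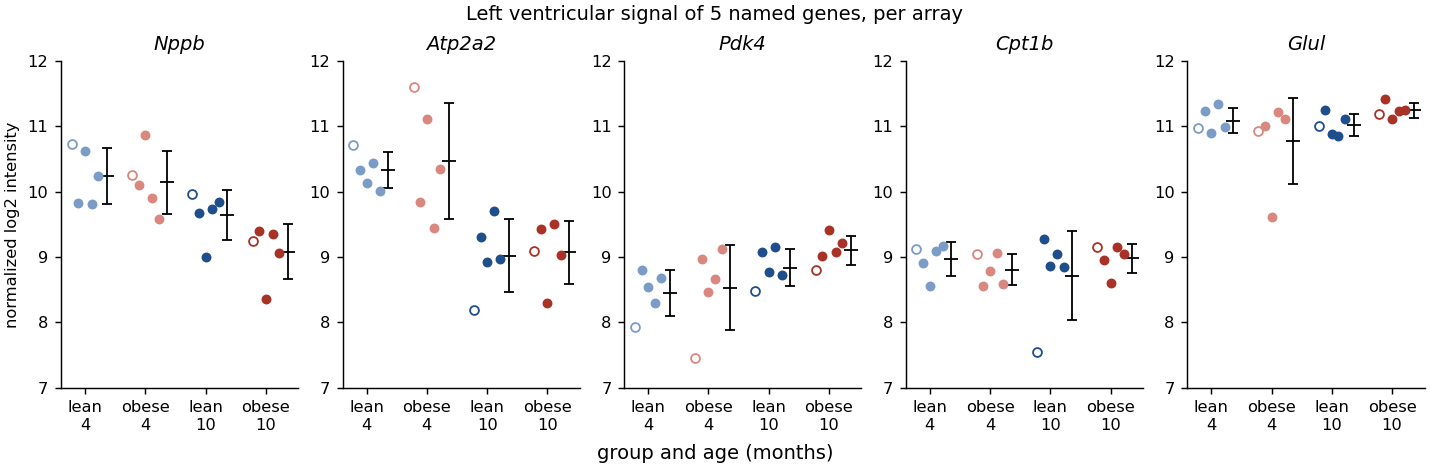
Normalized log2 intensity of the clones named Nppb, Atp2a2, Pdk4, Cpt1b and Glul in each of the 20 arrays, by group and age in months, with the mean and SD of each group of 5 as bars and the arrays numbered 1 as open circles. Nppb was 9.08 ± 0.42 in obese and 9.64 ± 0.37 in lean rats at 10 months, and Atp2a2 lay lower at 10 than at 4 months in both.

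The same comparison at 10 months asked how obese and lean ventricles differed when dilated cardiomyopathy begins. Nppb was 9.08 ± 0.42 (SD, n = 5) in obese and 9.64 ± 0.37 in lean rats, a difference of -0.56 ± 0.28 (SE) with a 95% interval from -1.14 to 0.02. It was lower in the obese rat in all 5 run pairs. With run pair as a block the difference was -0.56 ± 0.18 with an interval from -0.93 to -0.18, and with membrane and run pair as blocks it was -0.52 with an interval from -0.85 to -0.19, so both intervals left out 0 while the adjusted limma p was 1 in all 3 fits. Pdk4 differed by 0.26 ± 0.27, Cpt1b by 0.27 ± 0.27 with lean replicate 1 at 7.54 and the next array at 8.85, Glul by 0.22 ± 0.24 and Atp2a2 by 0.05 ± 0.35, each with a 95% interval that included 0 with and without the blocks. The sign of the Cpt1b difference rested on that array, as it was -0.02 without it. Glul was higher in the obese rat in all 5 run pairs. With run pair as a block and the 10-month arrays fitted alone, a setting chosen after the data had been seen, its interval ran from 0.01 to 0.44 and that of Nppb from -0.88 to -0.24, each with an adjusted limma p of 1.

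At 10 months limma passed 0 of 27648 clones, with 264 (0.95%) at an unadjusted p under 0.05 against a median of 724 in other splits, which could again break the run pairs. Among named genes Aebp1, which codes for a collagen-binding protein of the extracellular matrix, had the lowest p and differed by -0.95 ± 0.28, with all 5 obese arrays below the lean mean. The vasopressin gene Avp differed by -0.74 ± 0.25, the ADP-ribose hydrolase gene Nudt9 by -0.88, the zinc finger gene Ikzf5 by -0.89, the branched-chain keto acid dehydrogenase gene Dbt by -0.71 and the chaperone gene Dnajb6 by -0.65. Avp, Ikzf5, Dbt and Dnajb6 were lower in the obese rat in 5 of 5 run pairs. The D-amino acid oxidase gene Dao differed by 0.75 ± 0.27, the lymphocyte adaptor gene Skap1 by 0.74, the tenascin gene Tnn by 0.68 and the lysosomal galactosidase gene Glb1 by 0.58, the last 3 higher in 5 of 5 run pairs. All had an adjusted p of 1.

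No gene list passed at 10 months, where the lowest adjusted camera p was 0.406 and 0 of 20 lists had an unadjusted camera p under 0.05. That value was shared by apoptosis (mean 0.2 over 5 genes, above 0 in 5 of 5 run pairs), fatty acid oxidation (0.12 over 12 genes, 9 of them higher), renin-angiotensin, adrenergic and natriuretic signalling (-0.11 over 12 genes, 9 of them lower, positive in 0 of 5 run pairs) and heat shock (-0.09 over 16 genes, 8 lower, with a median of 0). With membrane and run pair as blocks these means were 0.2, 0.09, -0.1 and -0.08. Ubiquitin and proteasome genes had a mean of -0.11, and in them the muscle atrophy ligase gene Fbxo32 differed by -0.77 ± 0.34. The mean was 0.07 for fatty acid synthesis, glycolysis and glutamine metabolism, 0.05 for insulin and leptin signalling and inflammation, and 0.04 for extracellular matrix genes, in which the periostin gene Postn differed by 0.53 ± 0.27. PPAR alpha targets stood at 0, the citric acid cycle at -0.01, and cardiac stress, calcium handling and antioxidant genes at -0.02. Oxidative phosphorylation, ribosomal protein and clock genes stood at -0.03 and sarcomere genes at -0.07. The citric acid cycle, cardiac stress, calcium handling, antioxidant, ribosomal protein and clock lists differed in sign between mean and median or test. Cpt2 of fatty acid oxidation differed by 0.48 ± 0.31, Sdha of the citric acid cycle by 0.56 ± 0.28, the clock gene Bmal1 by -0.58 ± 0.25 and the small heat shock protein gene Hspb1, which had 1 of 2 other clones with the same sign, by -0.57 ± 0.29. The lowest adjusted fry p was 0.232, for apoptosis, and adjusted over the list alone 0 members passed.

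**Figure D2:**
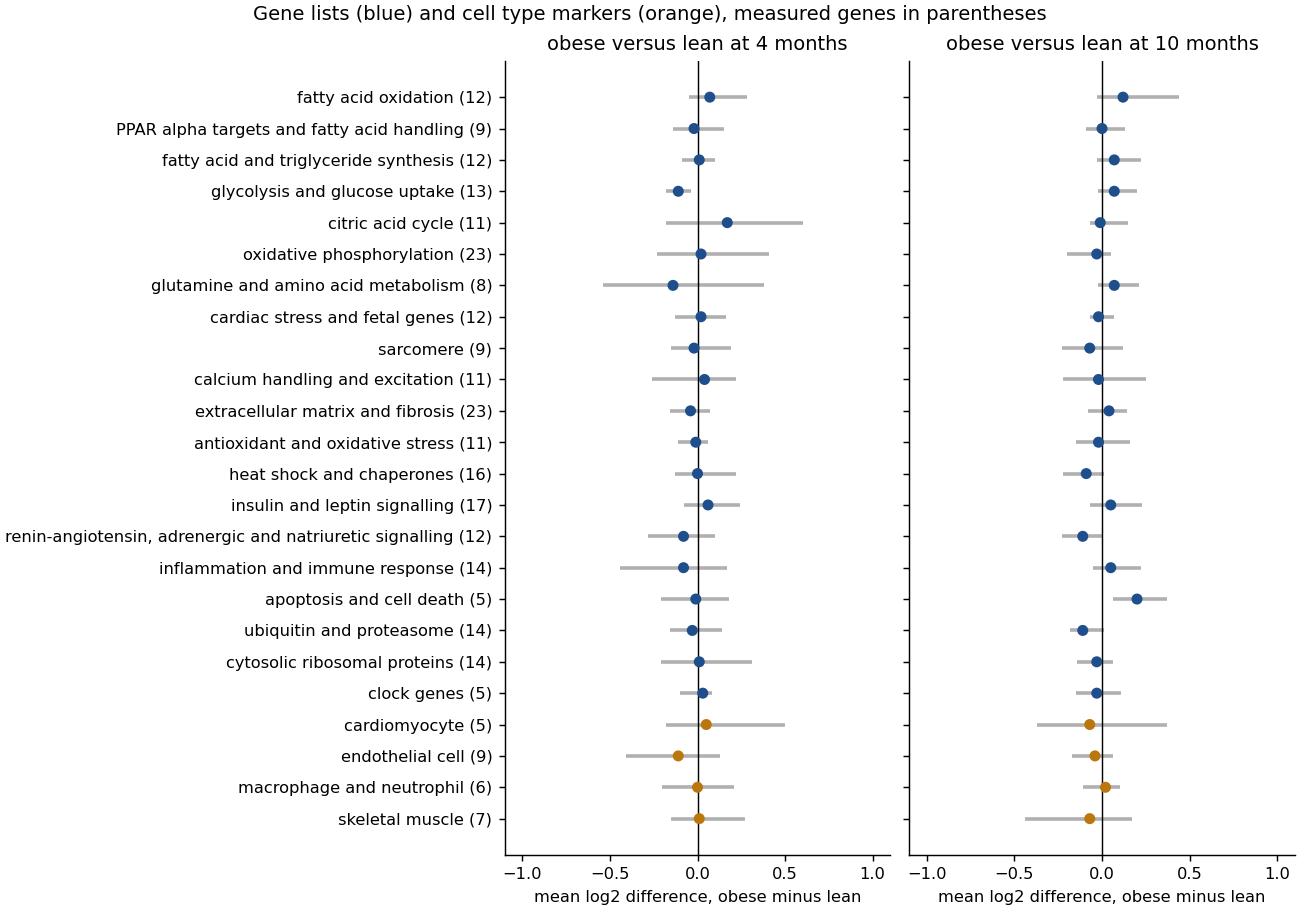
Mean log2 difference, obese minus lean, of each tested gene list (blue) and cell type marker list (orange) at 4 and at 10 months, with the measured genes in parentheses and grey bars from the lowest to the highest of the 5 run pairs. The means lie between -0.14 and 0.2, and none passed camera or fry.

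The markers of cell types likewise did not separate obese from lean rats. Endothelial markers (9 genes) had a mean of -0.11 at 4 months and -0.04 at 10 months, with adjusted camera p values of 0.605 and 0.641 and 6 members lower at both ages. Egfl7, a factor secreted by endothelium, differed by -0.53 ± 0.24 at 4 months. Cardiomyocyte markers (5 genes) had means of 0.05 and -0.07, macrophage and neutrophil markers (6 genes) 0 and 0.02, and skeletal muscle markers (7 genes) 0.01 and -0.07 at 4 and 10 months. Camera and fry passed 0 of the 4 marker lists at each age, and 0 of them had an unadjusted camera p under 0.05. Lists with fewer than 5 measured genes were not tested. At 4 and 10 months their means were 0.28 and 0.22 for fibroblast (3 genes), -0.24 and 0.15 for adipocyte (4), -0.21 and 0.02 for lymphocyte (2), -0.12 and 0.03 for smooth muscle (4), -0.09 and -0.11 for red blood cell (3), -0.08 and 0.1 for liver (3) and -0.01 and -0.03 for atrial muscle markers (3). Mitochondrially encoded genes and lung markers had 0 measured members.

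Whether the obese-lean difference depended on age was tested as an interaction, the difference at 10 months minus that at 4 months. Dystroglycan (Dag1) had the lowest p, with an interaction of 1.22 ± 0.44. The clock gene Bmal1, at 0.41 at 4 months and -0.58 at 10 months, had an interaction of -0.99 ± 0.35. Hspb1 (-1.07 ± 0.41), the phosphatase gene Ptpn22 (-1.32 ± 0.5) and Ikzf5 (-1.18 ± 0.44) followed. Limma passed 0 clones, with 258 at an unadjusted p under 0.05, and these genes had an adjusted p of 1. Adjusted over the list alone, Bmal1 passed among the 5 clock genes, the only member to do so in the 20 lists. Glutamine and amino acid metabolism had a mean interaction of 0.21 (7 of 8 members positive) with an adjusted camera p of 0.619, the lowest of the lists and shared with others. The marker lists reached 0.966. The obese-lean differences at the 2 ages correlated at 0.03 across clones and had the same sign in 51.6% of them.

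Averaged over both ages, with 10 obese against 10 lean arrays, Pbxip1 differed by -0.53 ± 0.17 and Ppfia1 by -0.56 ± 0.19. The kinase gene Btk of B lymphocytes differed by 0.57 ± 0.2 and the Z-disc protein gene Myoz1 by 0.55 ± 0.2. Rmdn2 differed by 0.59 ± 0.22 (0.43 without lean 4-month replicate 5). It was higher in the obese rat in 10 of 10 run pairs. The Fc receptor gene Fcgr2b was lower in 10 of 10, by a difference of only -0.23 ± 0.09, and the osteopontin gene Spp1 differed by 0.43 ± 0.2. Limma passed 0 clones, with 303 at an unadjusted p under 0.05, and all these genes had an adjusted p of 1. The lowest adjusted camera p was 0.559 for gene lists, as for renin-angiotensin signalling (mean -0.1, positive in 2 of 10 run pairs), and 0.244 for markers (endothelial, mean -0.08).

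In lean rats the comparison of 10 with 4 months asked which transcripts differed with age without obesity. Pdia5, for a protein disulphide isomerase of the endoplasmic reticulum, was 9.42 ± 0.51 (SD, n = 5) at 10 and 7.69 ± 0.08 at 4 months and rose by 1.73 ± 0.27 (SE; adjusted limma p 0.00285). Wdr70, a WD repeat protein gene, rose by 1.55 ± 0.28 (adjusted p 0.011), Elmod1 by 1.42 ± 0.28 (0.0236), the replication origin gene Orc1 by 1.38 ± 0.28 (0.0318), the magnesium transporter gene Nipa2 by 1.36 ± 0.29 (0.0374) and the G-protein modulator gene Gpsm3 by 1.45 ± 0.31 (0.0387). Lmod1, for an actin nucleator of smooth muscle, fell by 2.04 ± 0.41 (0.0292) and the transcription cofactor gene Taf5l1 fell by 1.73 ± 0.35 (0.0315), with 4-month replicate 1 at 10.92 and the next array at 8.93. Without that array Taf5l1 differed by -1.3 with an adjusted p of 0.056, so its call rested on it. Each of these 8 genes lay on the stated side of the 4-month mean in 5 of 5 arrays, but 7 of the 8, all except Pdia5, were no longer called without lean 10-month replicate 2, and likewise without replicate 4. Altogether 77 clones passed, 68 higher and 9 lower, of which 18 carried gene names (14 higher, 4 lower), and 3383 had an unadjusted p under 0.05. The split depended on the setting, with 227 higher and 168 lower without background correction, 515 and 232 with array weights, 475 and 336 without the 4 arrays numbered 1 and 141 and 63 without obese 4-month replicate 1. Without lean 4-month replicate 3 the count was 15, and without lean 10-month replicate 1 it was 223.

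Among genes of the fixed lists in lean rats, Atp2a2 was 9.02 ± 0.56 at 10 and 10.33 ± 0.28 at 4 months, a difference of -1.31 ± 0.35 (adjusted p 0.102, below the 4-month mean in 5 of 5 arrays). Of the 4 other Atp2a2 clones, 3 had the same sign. Nppb differed by -0.6 ± 0.28 (adjusted p 0.391), Pdk4 by 0.39, Cpt1b by -0.26 (0.04 without lean 10-month replicate 1) and Glul by -0.07. Adjusted over the list alone, 4 members passed, which were Atp2a2 and the potassium channel gene Kcnd3 (0.81 ± 0.26) in calcium handling, the citrate synthase gene Cs (0.36 ± 0.11) and the clock output gene Tef (0.81 ± 0.23), where the other clones of Cs and Tef had the opposite sign. Camera passed 0 of 20 gene lists, with a lowest adjusted p of 0.979 and 0 lists at an unadjusted p under 0.05, and the lowest adjusted fry p was 0.303. List means ran from -0.21 (glutamine and amino acid metabolism) to 0.18 (ribosomal proteins).

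In obese rats the same comparison asked which transcripts differed with age in the presence of obesity. Gpsm3 rose by 1.72 ± 0.31 (adjusted limma p 0.0096), from 8.4 ± 0.49 to 10.12 ± 0.29 (SD, n = 5). Nipa2 rose by 1.57 ± 0.29 (0.00976), Wdr70 by 1.39 ± 0.28 (0.0199), the phosphatase-related gene Plppr3 by 1.48 ± 0.3 (0.0234), the microtubule-binding protein gene Clasp2 by 1.4 ± 0.31 (0.0364) and Samm50, of the mitochondrial outer membrane, by 1.48 ± 0.35 (0.0448). The ubiquitin peptidase gene Usp54 fell by 1.86 ± 0.36 (0.0154), the asparagine synthetase gene Asns fell by 1.79 ± 0.41 (0.0386), Ankrd40 fell by 1.62 ± 0.37 (0.0386), the vesicle priming gene Cadps fell by 1.41 ± 0.31 (0.0333), the mitochondrial shape gene Tmem11 fell by 1.39 ± 0.31 (0.0333), the Notch target gene Hes5 fell by 1.36 ± 0.3 (0.0333) and the succinyl-CoA ligase gene Suclg1 fell by 1.2 ± 0.28 (0.0421), with its other clone of opposite sign. All lay on that side of the 4-month mean in 5 of 5 arrays, but none of the 13 was called without obese 10-month replicate 3. With the 2 arrays numbered 3 averaged 11 of the 13 were lost, all except Gpsm3 and Nipa2, and with local trends removed 9 were lost. Suclg1 was called in 20 of 39 other settings and Samm50 in 16 of 41. In total 192 clones passed, 131 higher and 61 lower, of which 50 carried gene names (29 higher, 21 lower), with 4472 at an unadjusted p under 0.05. After scaling to the 75th percentile in place of quantile normalization the split was 70 higher and 64 lower, and with median scaling it was 86 and 11. It was 489 higher and 500 lower without background correction, 807 and 424 without the 4 arrays numbered 1, 72 and 14 with local trends removed, 28 and 4 with the arrays numbered 3 averaged, 53 and 7 without obese 4-month replicate 1 and 23 and 19 from named clones alone. Without obese 10-month replicate 3 the count was 25, and without obese 4-month replicate 4 it was 413. The interaction test passed 0 clones, so the age effect was not shown to differ between obese and lean rats.

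Atp2a2 was 9.07 ± 0.48 at 10 and 10.47 ± 0.89 at 4 months in obese rats, a difference of -1.4 ± 0.35 (adjusted p 0.0572, lower in 5 of 5 arrays), and all 4 other Atp2a2 clones had the same sign. Nppb differed by -1.06 ± 0.28 (adjusted p 0.0762, lower in 5 of 5 arrays), Pdk4 by 0.57 ± 0.27, Glul by 0.47 ± 0.24 (0.17 without obese 4-month replicate 3) and Cpt1b by 0.18 ± 0.27. Adjusted over the list alone, 15 list members passed. Among them were Suclg1 and Idh3a (-0.87 ± 0.27) of the citric acid cycle, with Cs higher (0.32 ± 0.11), Asns, Nppb in 2 lists, Atp2a2 and Kcnd3 (0.76 ± 0.26), Hspb8 (0.57 ± 0.16), the signal transducer gene Stat3 (-0.75 ± 0.22), Eef1a1 (1.34 ± 0.37), Rps24 (0.62 ± 0.18), Bmal1 (-0.8 ± 0.25) and Tef (0.78 ± 0.23). None of the other clones of Cs, Stat3, Rps24 and Tef had the same sign as the clone printed. Camera passed 0 of 20 gene lists, with a lowest adjusted p of 0.97 and 0 lists at an unadjusted p under 0.05, and the lowest adjusted fry p was 0.151. List means ran from -0.27 (citric acid cycle, 9 of 11 members lower) to 0.15 (ribosomal proteins).

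Macrophage and neutrophil markers lay higher and endothelial markers lower at 10 months, and neither list passed. The former had a mean of 0.31 in lean and 0.33 in obese rats, with 5 of 6 members higher in both and adjusted camera p values of 0.103 and 0.222. Their adjusted fry p was 0.0869 and 0.0716, and with the estimated correlation the adjusted p was 0.392 and 0.515. The macrophage gene Aif1 differed by 0.91 ± 0.25 and 0.88 ± 0.25, and it passed adjusted over the list alone in both. Endothelial markers had means of -0.27 and -0.21, with Tie1 at -0.85 ± 0.3 and Cdh5 at -0.72 ± 0.27 in lean rats. Camera passed 0 of 4 marker lists in each, and 1 list in lean and 0 in obese rats had an unadjusted camera p under 0.05.

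**Figure D3:**
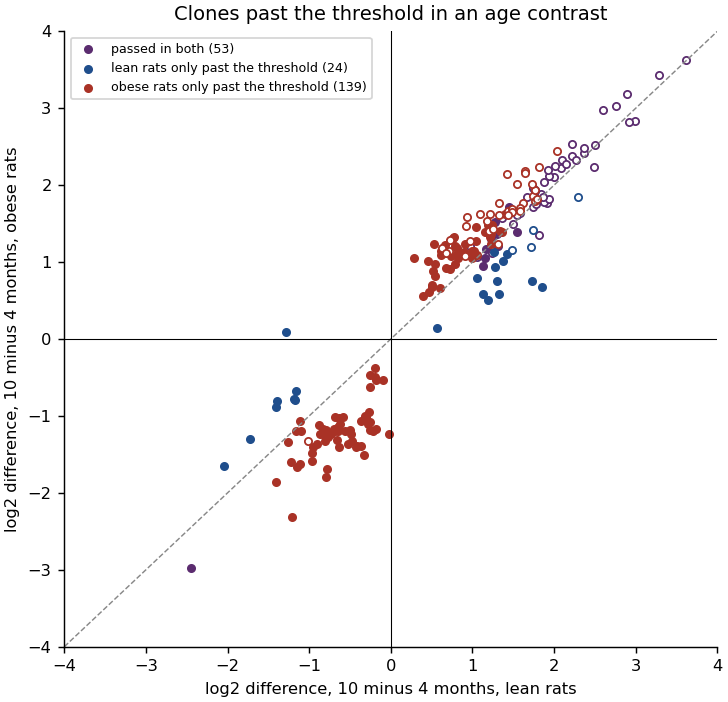
Log2 difference between 10 and 4 months in lean (horizontal axis) and obese (vertical axis) rats for the 216 clones that passed in at least 1 of them, 53 in both, 24 in lean and 139 in obese rats alone. Open circles mark the 81 clones at position 2 of the spotting block, most of them at the upper right, and the dashed line marks equal differences.

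The clones called with age were then compared between lean and obese rats. Of the 216 called in either, 53 passed in both and 215 had the same sign in both. Of the 53, 52 were higher, where independent comparisons would share 0.32 higher clones if calls were spread evenly over the array. They were not, as position 2 of the spotting block held 81 of the 216, so block position also stays open as a source of this overlap. The lean and obese arrays of an age shared run pairs and membranes, so these comparisons were not independent, and the shared runs were not separated from shared age effects. The age differences in lean and obese rats correlated at 0.74 across the 27648 clones and had the same sign in 74.4%. Of the 12 clone positions in a block, position 2 held 46 of the 77 and 77 of the 192 clones, and its 2304 clones had mean differences of 0.31 in lean and 0.34 in obese rats. With each position centred, 48 and 107 clones passed, but this takes out only the mean of a position over the whole array. Of the genes printed above as called, Nipa2 lay at position 2, and with the positions centred its call was lost in lean and kept in obese rats, while that of Suclg1, at position 6, was lost. Named clones not printed above also passed there in both lean and obese rats. They were Serp1 (1.93 and 2.2), Tuba1c (1.87 and 2.04) and Rpl19 (0.97 and 1.21). The rises of Serp1 and Tuba1c were larger than those of all genes printed above as called. In obese rats each of these clones at position 2 had an adjusted limma p of 0.00548, lower than any printed above for that contrast. No run date held rats of both ages, so age cannot be told apart from the period in which the arrays were run. The ratio of intensity to background also parted the ages, at 1.57 to 2.59 at 4 and 1.12 to 1.54 at 10 months. With run pair as a random block 112 and 206 clones passed, and with membrane as a random block 88 and 199.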

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

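The splits of the arrays for the obese-lean clone counts, the search for run dates shared by both ages, the blocks for membrane and run pair together, the fits without arrays numbered 1, the centring of block positions, the removal of local trends with the bound used to read it, and the use of interval widths to read the counts of 0 were chosen only after the results they test, or the data, had been seen.

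Values of 1 array that stood far from the other 4 of its group were found in 31 of 452 groups of values (6.9%), where chance gives about 1 in 20. The 4 arrays numbered 1 held 20 of the 31, and 13 of these were on the arrays numbered 1 at 4 months. The ratios below are the gap to the nearest other array over the range of the group. The median correlation with the other arrays of the group was lowest in replicate 1 of lean 4-month (0.82 against 0.92 for the next, ratio 0.96), lean 10-month (0.88 against 0.93, ratio 0.93) and obese 10-month rats (0.89 against 0.94, ratio 0.94). Background was highest in replicate 1 of lean 4-month rats (2009 against 721, ratio 0.83) and of lean 10-month rats (3224 against 1127, ratio 0.87).

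Among single genes, the clone of the caspase gene Casp9 was low in replicate 1 of obese 4-month (8.08 against 11.12, ratio 0.85) and lean 4-month rats (8.92 against 10.92, ratio 0.73) and high in replicate 1 of lean 10-month rats (11.64 against 10.5, ratio 0.84). In replicate 1 of lean 10-month rats Cpt1b (ratio 0.76) and Glb1 (0.81) were low. In replicate 1 of 4-month rats Nudt9 was high in the obese (0.8) and Taf5l1 high in the lean array (10.92 against 8.93, ratio 0.81). In other arrays, Glul was low in obese 4-month replicate 3 (9.61 against 10.93, ratio 0.82), Nr3c2 high in obese 4-month replicate 2 (0.84) and Lpar3 low in lean 4-month replicate 4 (0.78). Rmdn2 (0.81) and Sucla2 (0.71) were low in lean 4-month replicate 5, and Avp was low in lean 10-month replicate 2 (0.77). In obese 10-month rats Aebp1 was high (0.88) and Susd6 low (0.71) in replicate 3b, and Postn was low in replicate 5 (0.75).

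Among list means, replicate 1 of lean 4-month rats was lowest for fatty acid and triglyceride synthesis (ratio 0.75), glycolysis (0.86), cardiac stress genes (0.74) and antioxidant genes (0.76), and highest for inflammation (0.74). Replicate 1 of obese 4-month rats was lowest for glycolysis (0.78) and for insulin and leptin signalling (0.74). In lean 10-month rats, replicate 1 was lowest for extracellular matrix genes (0.77), and replicate 5 was lowest for inflammation (0.89) and highest for renin-angiotensin signalling (0.84).

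Of the 100 splits of the 10 lean arrays into groups of 5, 2 called at least 77 clones, the real one included. A count this high was rare among the splits, but the highest other split called 244, so the splits alone do not exclude chance. That split set 4-month replicates 1 to 4 with 10-month replicate 1 against the rest, so it stayed near the split by age. What raised its count was not tested, and only 3 of the other splits called any clone. In obese rats 1 of 100 splits, the real one, called 192 clones, and the highest other called 110. That other split set 4-month replicates 1, 2, 3 and 5 with 10-month replicate 1 against the rest, also near the split by age. As no run date held both ages, neither rank parts age from the period of the runs.

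Clones with a difference between 10 and 4 months may reflect age or the period and membranes of the runs. The tables argue against local trends as the whole cause, while the 4-month arrays numbered 1 and position in the block stay open. After position in the block was centred, 100 of the 192 clones called in obese rats were still called. The median size of the 192 went from 1.36 to 1.27. Without both 4-month arrays numbered 1, 132 of the 192 were still called. Without obese 4-month replicate 1 alone, 60 clones were called and only 54 of the 192 were among them. How far the calls rest on that array was thus not settled. After local trends on the membrane were removed all 192 kept their sign, with a median size of 1.36 ± 0.56 (SD) before and 1.21 ± 0.59 after and a median ratio of 0.89 (quartiles 0.79 and 0.94). Yet only 69 still passed and 132 had an adjusted p under 0.10, so a part of local trends in these calls stays open. Run period and membranes stay open: 0 run dates held arrays of both ages, so age cannot be told apart from the period, and a difference due to age itself was not tested separately.

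For the absence of called clones between obese and lean rats, the real count of 0 meant that all 100 of 100 splits had to give at least as many in each of the 4 contrasts, which says nothing about chance. At an unadjusted p under 0.05, 91 of 100 splits at 4 months and 96 at 10 months had at least the 384 and 264 clones of the real split. The medians were 1544 and 724 in the others. Those splits could break the run pairs, which the real split kept balanced, so these counts are not alike. The highest other split called 211 clones at 4 months, 42 at 10 months, 8 for the interaction and 224 for the average, against 0 in each real one, but only 8, 4, 3 and 6 of the splits called any clone. The split of 42 at 10 months was that of the 2 membranes, but the split of 211 at 4 months had only 3 of 5 arrays of a membrane on 1 side and is not accounted for by membrane, whose own split called 118 there, and in fits with run pair and obesity 687 and 713 clones differed between membranes. With membrane and run pair as blocks 0 clones were called at 4 or 10 months, with 1374 and 886 at an unadjusted p under 0.05, and without the 4 arrays numbered 1 again 0, with 668 and 302. The median 95% interval was ±0.44 and ±0.57 in these fits against ±0.59. The noise removed by the blocks was thus not the whole cause of the absence. Without the 4 arrays numbered 1 the interval hardly narrowed, so the count of 0 there decides nothing on their noise. Effects too small for 5 arrays per group stay open. Even in arrays simulated with independent noise, only 31% of 2-fold changes were found at 4 months.

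With camera 0 lists passed in every contrast, so all 100 of 100 splits had to pass at least as many, which says nothing about chance. The highest other split passed 3 gene lists at 4 months, 3 at 10 months, 4 for the interaction, 3 for the average, 1 for age in lean and 3 for age in obese rats. For the marker lists, it passed 1, 2, 2, 1, 2 and 3 in the same order.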

How the results depend on the processing

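Of 53 other settings, 12 were chosen only after the data had been seen, which were the membrane blocks, run pair as a block in each age alone, the geometry groups as a term, the random blocks, the fits without several arrays numbered 1 or with their labels exchanged, removal of local trends, centring of block position and named clones alone. Between obese and lean rats, limma called 0 clones in all 188 recomputed counts over the 4 contrasts at the adjusted threshold, and an unadjusted p under 0.001 gave 1 clone at 4 months and 1 at 10 months. The deviations of the 2 arrays of a run pair correlated above 0.1 in 7 of 10 pairs (median 0.28 against -0.05 between pairs), and 9 of 20 arrays correlated best with their own pair, a hint from the data of a shared run, while not every pair did so and the fit without blocks was kept. With the label number as a replicate block, and with run pair as a block, 0 clones were called at each age, 1119 and 1031 at an unadjusted p under 0.05 in the former. Age cannot be fitted with these fixed blocks, as each was defined within 1 age. With the 2 geometry groups as a term 98 and 220 clones were called for age in lean and obese rats, 77 and 190 of them among the 77 and 192. The counts for age in lean and obese rats, 77 and 192, moved to 395 and 989 without background correction, 41 and 103 with the background-subtracted column, 234 and 430 with cyclic loess, 18 and 94 in the 13824 brighter clones, 25 and 66 from the series matrix, 747 and 627 with array weights, 235 and 612 at an adjusted p under 0.10, and 257 and 358 at an unadjusted p under 0.001. Median scaling, which moved the median of all clones by 0.19 and 0.21, left 73 and 97, and averaging the obese 10-month arrays numbered 3 left 66 and 32. The added settings gave 811 and 1231 without the 4 arrays numbered 1, 46 and 86 after removal of local trends, 48 and 107 with block position centred, and 13 and 42 from named clones alone, where fewer clones were tested. The cause of the other moves was not tested. Leaving out 1 array gave 15 to 223 in lean and 25 to 413 in obese rats. For lean rats the counts beyond 1.5 times came without lean 4-month replicates 1 (30), 2 (21) and 3 (15), lean 10-month replicates 1 (223), 2 (16), 3 (28), 4 (16) and 5 (26), obese 4-month replicate 1 (204), and obese 10-month replicates 1 (128) and 2 (43). For obese rats they came without obese 4-month replicates 1 (60), 3 (41) and 4 (413), obese 10-month replicates 1 (302), 2 (49), 3 (25), 3b (45) and 5 (35), lean 4-month replicate 1 (397) and lean 10-month replicate 2 (122). In lean rats Pdia5 was called in 39 of 40 settings, Wdr70 in 38 of 41, Elmod1 in 34 of 41, Lmod1 in 32 of 41, Orc1 in 31 of 40, Taf5l1 in 30 of 40, Nipa2 in 30 of 41 and Gpsm3 in 26 of 41. The call of Pdia5 was lost only without background correction. In obese rats Gpsm3 and Nipa2 were called in 40 of 41, Usp54 in 38 of 41, Wdr70 in 36 of 41, Plppr3 in 34 of 41, Hes5 in 31 of 41, Clasp2 in 29 of 41, Asns in 28 of 41, Ankrd40 in 27 of 40, Tmem11 and Cadps in 25 of 39, Suclg1 in 20 of 39 and Samm50 in 16 of 41. None of these 21 calls changed sign, but all 13 in obese rats were lost without obese 10-month replicate 3, 11 with the arrays numbered 3 averaged and 9 without local trends, and 7 of the 8 in lean rats without lean 10-month replicate 2 or 4. Their sizes depended on the setting. Pdia5 in lean rats ran from 0.45 to 2.08, and in obese rats Cadps ran from -1.56 to -0.19 and Tmem11 from -1.76 to -0.35. Others moved less, such as Clasp2 in obese rats, from 0.97 to 1.65. Gene lists passing rose from 0 to 1 for age in obese rats (oxidative phosphorylation) with cyclic loess and without the 4 arrays numbered 1, and to 1 at 4 months (citric acid cycle) without lean 4-month replicate 4, and ranged from 0 to 1 there when 1 array was left out. Marker lists passing for age rose to 2 in lean and 1 in obese rats with the series matrix, to 1 in lean rats without local trends, and ranged from 0 to 2 in lean rats when 1 array was left out (2 without lean 10-month replicate 5) and from 0 to 1 for the average (1 without obese 10-month replicate 5). The cardiomyocyte list for age in lean rats turned from -0.01 to 0.5 with the series matrix, and Casp9 for age in obese rats from 0.1 to -0.71 without the 4 arrays numbered 1, both then past the threshold. Values past no threshold under either setting changed sign in 204 of 6610 gene values at 4 months and 135 of 6402 at 10 months. Signal over background, 1.57 to 2.59 at 4 and 1.12 to 1.54 at 10 months, limits how small a difference in a dim clone can be read. On obese 4-month replicate 1 the centre spots had a higher ratio (1.75) than the clone spots (1.71). Only 11.2% of its clones lay above the 95th percentile of the centre spots. With a filter for clones above the level of these spots, 23652 were tested. Of them 0 were called between obese and lean rats, and 85 and 166 with age in lean and obese rats.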

Other observations

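The exchange of labels and the regressions below were chosen after the header letters had been seen, before their results.

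The headers carried a letter for obese or lean that matched the label on 18 of 20 arrays and opposed it on both 4-month arrays numbered 1. These arrays may have been exchanged between labels, and the coefficient of their labelled difference on the obese-lean effect of the other 4 pairs at 4 months was -0.14, against an SD of 0.18 among the other 9 pairs, which ranged from -0.44 to 0.09. As only 3 of those 9 pairs lay above 0, the test could not tell an exchange from none, and both readings stay open. The coefficient on the membrane effect, 0.89 against 0.34 to 0.86 in the other pairs, decides nothing on exchanged membranes, since the membrane was inferred from the same file as the signal. With the labels exchanged, 0 clones were called between obese and lean rats, and 78 and 157 with age in lean and obese rats.

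The arrays numbered 3 and 3b of obese 10-month rats correlated at 0.94, within the range of 0.86 to 0.96 for that group, and were treated as different rats. The obese and lean arrays of 1 run pair had deviations from their group means that correlated at a median of 0.28 over the 10 pairs, against -0.05 over 40 combinations of different pairs. The pairs numbered 1 had the highest values, 0.71 at 4 and 0.5 at 10 months.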
